A study of Arabidopsis thaliana with 12 samples.

How the data were processed

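Total RNA of 12 Arabidopsis samples was hybridised to single-channel arrays, 6 from plants given water and 6 from plants given 2 µM staurosporine for 4 h, all followed by 25 mM ascorbate at pH 5.5 for 4 h, per the labels. Groups and replicate numbers 1 to 6 were taken from the sample titles and source descriptions. The tissue, growth conditions, scanner and statistical methods are not given in the sources used here. The deposited series table holds 1 linear intensity per probe and array, and what the authors did to make these intensities (background correction, scaling, averaging of spots) is not given in the sources used here. The values run from 0 to about 100, and 8 of the 12 arrays reach that upper end at 1 or 2 probes, so the deposited intensities appear to be relative to a ceiling that was set before deposit. The scale therefore has no absolute unit, and differences are read only as ratios between groups for the same probe. All 12 columns were used.

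The array medians differed by more than 5%, so the intensities were quantile normalized between arrays, as fixed before the data were examined. Values listed at 0 were set to the 1st percentile of the positive normalized values of their array, positive values under that floor were raised to it, and log2 was taken. The floors differ between arrays, from -9.05 to -4.15 on the log2 scale, so a probe listed at 0 on all 12 arrays gets a fitted log2 change of -1.12 that is no measurement. There were 109 such probes, and none of them is named with a change. For 2584 probes every array was above 0. The number of arrays limits the precision, and dim probes near the floor are the least certain.

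Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no block), with Benjamini-Hochberg adjustment over 3439 probes and a threshold of 0.05. Changes are log2 of staurosporine over water, with the SE of the fit over 12 arrays. Means and SDs were taken over the 3 number pairs of each group on normalized linear intensities, so a ratio of means can differ from the fold, which is 2 raised to the fitted change. Gene lists with at least 5 measured genes were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry. Only 1 of 27 lists reached that size, and only by counting a gene that was at 0 on 11 of 12 arrays, so no list test is read. An outlying array in a group of 6 was sought with Dixon's ratio at 0.625.

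Probes were named through the platform annotation, which can be old, updated by gene identifier to the symbols of the TAIR10.1 assembly. Of the 3439 probes, 692 have 1 gene, 870 have several and 1877 have none listed there, and 690 of the 692 matched the assembly's gene table. No gene was named from a probe with several. Positions in the genome are not given, because no build is named for the arrays. AT2G25870 was the only gene with 2 probes, and these did not move together, with log2 changes of 1.37 (adjusted p 0.00250) and -0.35 (adjusted p 0.231). Named genes are the 15 largest rises and 15 largest falls among single-gene probes past the threshold, the 4 measured genes of lowest p in each list, and 4 peroxiredoxins and ascorbate peroxidases, which had no single-gene probe. Where probes had no single gene, the 2 that rose most and the 2 that fell most are given by number. This rule, the lists, the tests and the first set of other settings were fixed before the data were examined.

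Replicate numbers were checked in both directions. Arrays with the same number in both groups deviated together from their group means, with correlations of 0.374, 0.297, 0.337, 0.441, 0.534 and 0.545 for numbers 1 to 6, so the numbers pair arrays across groups, and a fit with the number as a block was an alternative. Over probes above 0 on all arrays these correlations were lower, from 0.158 to 0.273. Arrays of the same number pair with another number had 0.00466 to 0.094 there. Arrays 1 and 2, 3 and 4, and 5 and 6 within a group were also alike, with Spearman correlations of the deposited values of 0.889 to 0.987 within such pairs and 0.825 to 0.917 between arrays of other pairs in a group. Averaging these number pairs had been planned as an alternative. The design of 6 against 6 was kept for the main comparison as fixed, with the count after averaging beside it.

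The fit was tested on simulated data with the probe means and the spreads between and within number pairs seen here. With 200 of 3439 probes changed and 12 independent arrays, 44% of changes of 1 and 82% of changes of 2 log2 units were recovered, and 1.56% of the calls were false. With arrays in number pairs and no change at all, the fit over 12 arrays made 41.4 false calls on average in 20 runs (10 to 79), and the fit on averaged pairs 0.05 (at most 1). Averaged pairs recovered 3% of changes of 1 and 49% of changes of 2 log2 units. The simulated pair effects were drawn separately for each probe, without values at 0 and without likeness across groups. These counts of false calls therefore set no bound for the real arrays.

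Other settings fixed at the start were the deposited values without further normalization, centring on array medians, cyclic loess, an offset of 0.0391 added before log2 in place of the floor, leaving out the dimmest 25% of probes, the replicate number as a block, averaging numbers 1 and 2, 3 and 4, 5 and 6, averaging numbers 1 and 4, 2 and 5, 3 and 6, eBayes with trend and robust, array weights, leaving out each array in turn, stricter thresholds, and averaging probes of 1 gene. After the count with averaged pairs had been seen, 8 more were added. These were averaged pairs with the offset, averaged pairs without the dimmest probes, the number pair as a random block, a common floor, leaving out numbers 5 and 6, and a block for the 6 arrays of higher and the 6 of lower median, over 12 arrays and over averaged pairs, and averaged pairs with the number pair as a block. All 8 are reported.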

Results

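Transcript levels were measured in wild-type Arabidopsis thaliana of the Columbia background on single-channel arrays that carry 3439 probes. In 1 group of 6 arrays, plants received water for 4 h and then 25 mM ascorbate at pH 5.5 for 4 h. In the other group of 6 arrays, plants received 2 µM staurosporine for 4 h in place of water, followed by the same ascorbate treatment. Staurosporine is a broad inhibitor of protein kinases, and ascorbate is the main soluble antioxidant of plant cells and the electron donor of ascorbate peroxidases. The contrast asks which transcripts differ when kinases are inhibited before ascorbate is given. Plants without ascorbate were not analysed here, so no value below is a response to ascorbate itself. The deposited values are relative intensities with array medians of 0.252, 0.259, 0.383, 0.383, 0.419 and 0.416 in water replicates 1 to 6, and of 0.437, 0.431, 0.355, 0.351, 0.486 and 0.483 in staurosporine replicates 1 to 6. Between 10.3% and 15.2% of the probes of an array were listed at 0. Nothing in the labels says that the 6 arrays of a group came from separate plants, so the p-values measure only the spread between arrays, which may be technical. Levels are given as normalized intensity, as mean ± SD over the 3 means of replicates 1 and 2, 3 and 4, and 5 and 6 (called number pairs below), because the arrays within these pairs were on average more alike than others of their group.

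Staurosporine before ascorbate lowered the transcript of PSAN, the lumenal photosystem I subunit at the plastocyanin docking site, 3.32-fold, and that of LHB1B2, a light-harvesting chlorophyll a/b protein of photosystem II, 1.57-fold. It also lowered AT-HF, an enzyme of histidine synthesis, ETFQO, the mitochondrial ubiquinone oxidoreductase that accepts electrons from the electron-transfer flavoprotein, and the clock-controlled transcript CCL. ETFQO lost its call without further normalization and with arrays centred on their medians. LHB1B2 lost its call with the number pair as a random block (limma adjusted p 0.0975) and without numbers 5 and 6 of both groups (0.149). AT1G68660, which encodes the chloroplast Clp protease adaptor ClpS1, was 4.36-fold higher. With the number pairs averaged, none of the genes named so far passed an adjusted p of 0.05 in limma. With the 12 arrays taken as separate samples, 788 of 3439 probes (22.9%) passed an adjusted p of 0.05 in limma, 381 higher and 407 lower after staurosporine. With each number pair averaged as 1 sample, 9 probes passed, 4 higher and 5 lower, and none of these 9 carries a single annotated gene. That fit has no block for the number pairs shared by the groups; with such a block added after the data were seen, 2 of the 9 passed, probes 217 and 271, both lower. After the same averaging, 654 probes had an unadjusted p under 0.05. Other ways of averaging number pairs or modelling their likeness, chosen after that count was seen, gave between 5 and 191 probes. Leaving out numbers 5 and 6 of both groups gave 377 with the remaining arrays as separate samples. The share of higher probes among those called was 48.4%, but 60.6% without further normalization and 34.4% with arrays centred on their medians. The median log2 change of all probes was -0.12 after quantile normalization, 0.19 without it and -0.10 after centring.

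Among the probes with 1 annotated gene, 154 passed the test over 12 arrays, 76 higher and 78 lower. PSAN (AT5G64040) had the lowest adjusted p of the 30 genes with the largest changes. Its level was 1.76 ± 0.257 after water and 0.524 ± 0.00682 after staurosporine (n = 3 number pairs), a log2 change of -1.73 ± 0.13 (SE) with a limma adjusted p of 9.13e-06. AT2G47360 had the largest fall, from 0.706 ± 0.170 to 0.222 ± 0.211, a log2 change of -2.18 ± 0.59, and was listed at 0 on 2 staurosporine arrays; its adjusted p of 0.0216 rose to 0.0783 without further normalization. AT3G09250 fell from 1.21 ± 0.135 to 0.342 ± 0.0896, or 3.67-fold. AT-HF (AT4G26900), the imidazole glycerol phosphate synthase of histidine synthesis, fell from 1.33 ± 0.484 to 0.375 ± 0.140 with an adjusted p of 0.00168. ETFQO (AT2G43400) fell from 0.330 ± 0.0545 to 0.130 ± 0.0724 and was listed at 0 on 1 staurosporine array. Its adjusted p of 0.0260 rose to 0.144 without further normalization and to 0.0584 with arrays centred on their medians. The log2 changes of ETFQO in the 3 number pairs were -2.45, -2.21 and -0.43. Without numbers 5 and 6 of both groups its log2 change was -3.18 (adjusted p 0.0671). CCL (AT3G26740) fell from 9.51 ± 3.06 to 3.66 ± 1.73, with log2 changes of -0.54, -1.05 and -2.79 in the 3 number pairs. AT2G42490, a copper amine oxidase, had a log2 change of -1.34 ± 0.36, and its adjusted p of 0.0194 rose to 0.203 without further normalization. The log2 changes of AT4G22650, AT3G26580, AT3G57120, AT3G06200, AT1G24040, AT3G50350, AT5G27560 and AT1G67930 lay between -1.71 and -1.29, with adjusted p between 7.6e-05 and 0.0368. Without further normalization AT5G27560 (adjusted p 0.336) and AT1G67930 (0.184) did not pass, nor with arrays centred on their medians (0.107 and 0.0549). AT1G24040 went from -1.47 to -0.651 with array weights (adjusted p 0.159). Its call also ended without water replicate 1, 2, 3 or 4 or staurosporine replicate 4 or 5 (0.0534 to 0.0837), and that of AT1G67930 without water replicate 1, 2, 5 or 6 or staurosporine replicate 3, 4, 5 or 6 (0.0508 to 0.0667).

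Of the rises, AT4G05030 was the largest, from 0.0429 ± 0.0251 after water to 0.333 ± 0.167 after staurosporine (n = 3 number pairs), a log2 change of 3.02 ± 0.44 with a limma adjusted p of 0.000676. AT1G56460 rose from 0.0383 ± 0.0225 to 0.188 ± 0.0154, a log2 change of 2.44 ± 0.35. Both were listed at 0 on 2 of the 6 water arrays, so the size of these changes depends on how values of 0 were treated. With an offset added to every value in place of a floor, their log2 changes were 2.51 for AT4G05030 and 1.90 for AT1G56460. AT1G68660, the ClpS1 adaptor, was above 0 on every array and rose from 0.131 ± 0.0641 to 0.479 ± 0.0582, with a log2 change of 2.12 ± 0.38 and an adjusted p of 0.00250. AT4G09620 rose from 3.496 ± 0.547 to 11.4 ± 4.14, and AT3G52070 from 3.31 ± 0.634 to 8.69 ± 1.30. AT1G34270 had the most even rise over the number pairs, from 0.267 ± 0.0258 to 0.717 ± 0.0501, with log2 changes of 1.36, 1.48 and 1.42. The other 9 genes, AT1G58230, AT2G39100, AT3G61870, AT2G43180, AT2G01400, AT1G71910, AT5G66050, AT1G50770 and AT1G49850, had log2 changes between 1.39 and 1.69 and adjusted p between 0.00412 and 0.0354. With arrays centred on their medians AT2G43180 (0.0533) and AT3G52070 (0.0638) did not pass. AT2G43180 went from 1.59 to 0.86 with array weights (adjusted p 0.128), and its call also ended with cyclic loess (0.0569) and without water replicate 1 or 2 or staurosporine replicate 2, 3, 5 or 6 (0.0563 to 0.0761). Of the 30 genes, 25 passed without further normalization and 24 with centring. All 30 genes kept their sign in each of the 3 number pairs, as did 97.6% of all called probes. The 30 were picked by the test on these same arrays, so their shared signs and low unadjusted p are no separate support. Of the 30, 9 were listed at 0 on at least 1 array. With the number pairs averaged, none of the 30 passed in limma, with adjusted p between 0.0591 for PSAN and 0.265 for AT1G24040 and with an unadjusted p under 0.05 for 29 of them. None passed with the number pair as a block as well, with adjusted p between 0.158 and 0.254.

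**Figure D1:**
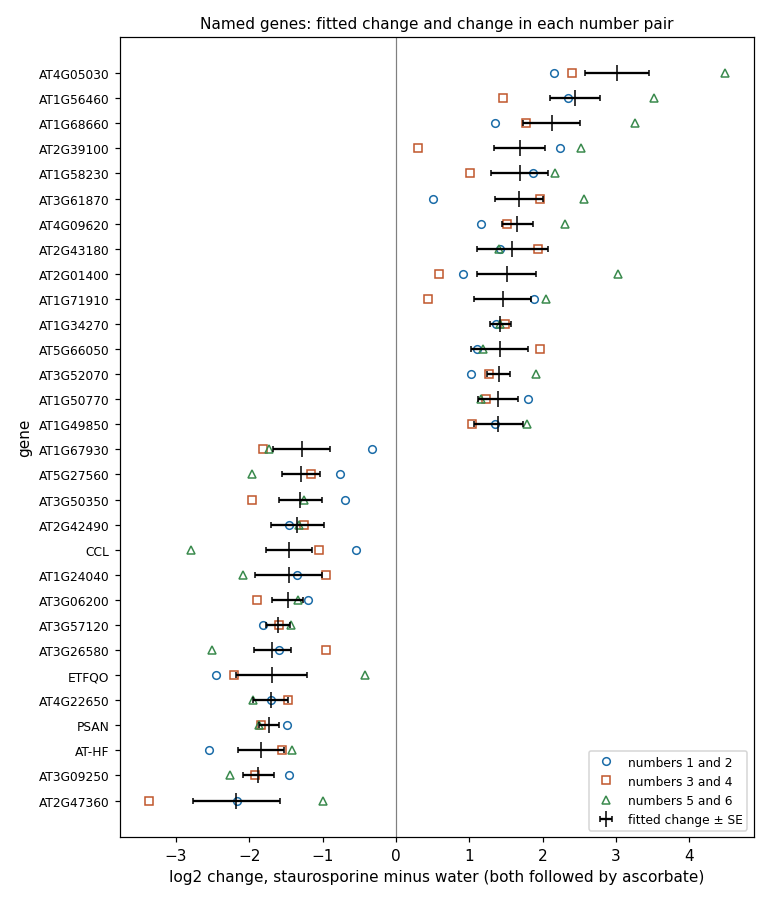
Log2 change after staurosporine relative to water, both followed by ascorbate (x axis), for the 15 genes with the largest rises and the 15 with the largest falls (y axis). Black bars give the fitted change ± SE over 12 arrays and open symbols the change in each number pair. All 30 genes, picked by the test on these arrays, have 3 symbols on 1 side of 0. The symbols of AT1G34270 lie closest together, between 1.36 and 1.48.

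Genes of the photosynthetic apparatus that could be named were few. Of 456 genes on 27 lists fixed beforehand, 18 had a probe of their own with a signal, and of these none passed as higher, 3 passed as lower and 15 did not pass. The only measured gene of the antenna list, LHB1B2 (AT2G34420), fell from 2.11 ± 0.567 to 1.31 ± 0.0826. Its log2 change was -0.65 ± 0.17, with a limma adjusted p of 0.0177 over all probes and an unadjusted p of 0.00243. A list with 1 measured gene leaves nothing to adjust over. The only measured gene of the photosystem I list was PSAN, which passed over all probes. Neither of the 2 measured genes of the photosystem II list passed, with log2 changes of -0.41 ± 0.19 for PSBY and 0.28 ± 0.14 for PSBW. With arrays centred on their medians PSBW was -0.27. PSB27, a photosystem II gene left off the list, had a log2 change of -0.80 ± 0.30. Its limma adjusted p was 0.077, 0.0162 with the replicate number as a block and 0.335 with the number pairs averaged. PRK, the phosphoribulokinase of the Calvin cycle, had a log2 change of -0.31 ± 0.23 and an adjusted p of 0.349. With the number pairs averaged, the adjusted p of LHB1B2 was 0.280 and its unadjusted p 0.0565.

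Both measured genes of the chlorophyll synthesis list had higher mean levels after staurosporine without passing over all probes. HEMA3 (AT2G31250), a gene of the same pathway left off that list, went the other way. It had a log2 change of -0.67 ± 0.28 and a limma adjusted p of 0.110. CHLM, the magnesium protoporphyrin IX methyltransferase, had a log2 change of 0.68 ± 0.25 with an adjusted p of 0.0707, and AT1G74470, the geranylgeranyl reductase, 0.36 ± 0.13 with 0.0684. Both passed at 0.0188 adjusted over the list alone but not with the number pairs averaged (0.146), and AT1G74470 was at -0.05 with arrays centred on their medians. For plastid ribosomal proteins, the only list with 5 genes above 0 on any array, 1 gene was lower and 4 did not pass. AT3G13120, ribosomal protein S10 of the plastid, went from 0.270 ± 0.0151 to 0.180 ± 0.0318 with an adjusted p of 0.0475, which was 0.0767 with the replicate number as a block, 0.157 with arrays centred on their medians and between 0.0542 and 0.0962 without any 1 array other than staurosporine replicate 3 or 6. AT1G29070 had a log2 change of 1.45 ± 0.61 and an adjusted p of 0.113, and AT5G65220 one of 0.11 ± 0.17. The size for AT1G29070 depends on how values of 0 were treated, since it was listed at 0 on 3 water arrays and 1 staurosporine array. AT1G64510 was at 0 on all 6 water arrays and 5 staurosporine arrays and is given no fold. The other 4 genes are under the minimum of 5 set for a test of the list, so the p of 0.985 that camera gave for all 5 says nothing about the list. None of these genes passed adjusted over the list alone.

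No listed redox gene with a probe of its own passed the test. Neither did the probes that carry several redox genes of a list, 3 of them for the ascorbate and glutathione cycle. Of 8 redox probes with a signal, probe 3511, with 2 genes, changed most, by a log2 change of -1.65 ± 0.64. It was listed at 0 on 2 staurosporine arrays. Its limma adjusted p was 0.0837, 0.0160 with the replicate number as a block and 0.296 with the number pairs averaged. GLDH, which catalyses the last step of ascorbate synthesis, had a log2 change of 0.60 ± 0.43 and an adjusted p of 0.328. AT3G52960, the chloroplast peroxiredoxin IIE, had a log2 change of 0.21 ± 0.31. In the thioredoxin system, NTRC, the NADPH-dependent reductase of 2-Cys peroxiredoxins, had a log2 change of -0.28 ± 0.26, and AT2G04700, the catalytic subunit of ferredoxin-thioredoxin reductase, one of -0.42 ± 0.50. Without further normalization these were 0.07 for NTRC and 0.12 for AT2G04700. APS4, an ATP sulfurylase, had a log2 change of -0.81 ± 0.29 and an adjusted p of 0.0661, and FATB, the acyl-ACP thioesterase of plastid fatty acid synthesis, -1.96 ± 0.70 with 0.0622. Each was the only measured gene of its list, so there was nothing to adjust over the list alone. The unadjusted limma p was 0.0170 for APS4 and 0.0155 for FATB (0.0861 and 0.0170 with the number pairs averaged). In both genes the change was small at numbers 3 and 4 (-0.05 for APS4 and -0.08 for FATB). FATB was listed at 0 on 1 staurosporine array, and with an offset in place of the floor its log2 change was -1.55. The 2-Cys peroxiredoxins and the chloroplast ascorbate peroxidases, which were to be named in any case, were not analysed here by name because no single-gene probe was assigned to them. The same holds for the lists of photorespiration, electron transport and ATP synthase, ascorbate and glutathione cycle, superoxide dismutase and catalase, carotenoids, chaperones and proteases, plastid import, plastid transcription and translation factors, starch, shikimate and tryptophan, jasmonate, stress and defence, kinase signalling, and the root, myrosin cell and trichome, and seed storage markers.

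**Figure D2:**
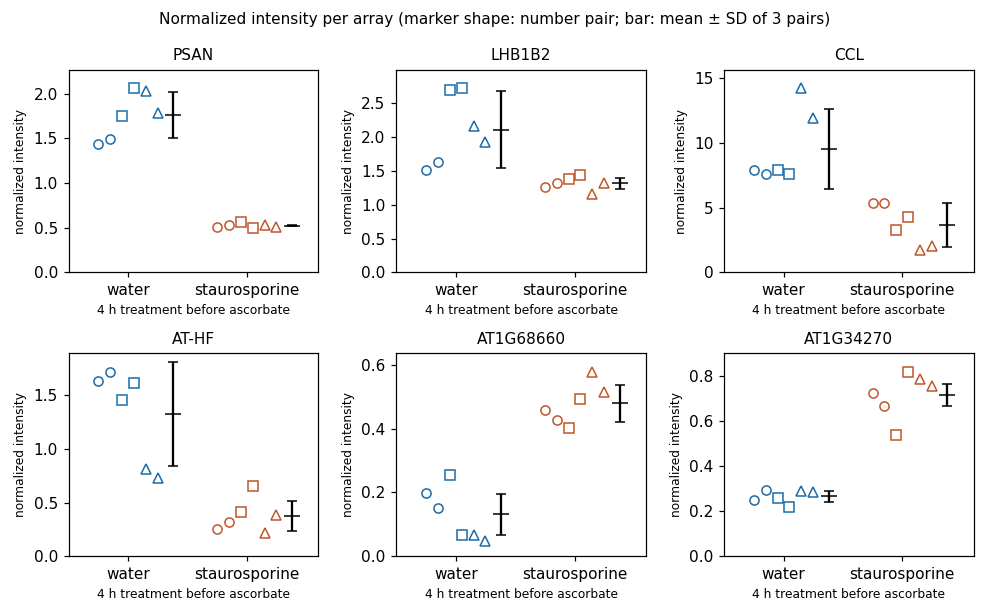
Normalized intensity (y axis, starting at 0) of 6 of the named genes on each of the 12 arrays by the 4 h treatment before ascorbate (x axis). Marker shapes give numbers 1 and 2 (circles), 3 and 4 (squares) and 5 and 6 (triangles), and black bars the mean ± SD of the 3 number pairs. PSAN lies between 1.43 and 2.06 after water and between 0.500 and 0.564 after staurosporine. In these 6 genes, all called on these same arrays, no staurosporine array reaches into the range of the water arrays. The ranges overlap in other called genes such as AT2G47360, with staurosporine replicate 5 at 0.554 and water replicate 3 at 0.331.

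The strongest changes belonged to probes without a single named gene. Probe 217 fell from 12.02 ± 1.81 to 0.500 ± 0.0671 (n = 3 number pairs), or 24.1-fold, with a limma adjusted p of 4.07e-09 over 12 arrays and 0.00408 with the number pairs averaged. Probe 271 fell from 9.43 ± 2.19 to 0.291 ± 0.132, or 34.8-fold, with an adjusted p of 0.0137 after averaging. Probe 2399 was listed at 0 on all 6 water arrays and reached 0.495 ± 0.0244 after staurosporine, with an adjusted p of 0.0138 after averaging and 0.109 with the number pair as a block as well. Probe 68 was listed at 0 on 4 water arrays and reached 0.478 ± 0.455, with an adjusted p of 0.107 after averaging. In all, 634 of the 788 called probes carry several genes or none in the platform annotation used here. That is about the same share as over the whole array, where 870 of 3439 probes carry several and 1877 none.

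The arrays of a group were not equally alike. The correlation of deviations from the group mean averaged 0.474 (0.157 to 0.785) within the 6 number pairs and -0.358 (-0.716 to 0.186) between arrays of different number pairs in a group. Deviations from a group mean cancel across the arrays of that group, so likeness within pairs makes the values between pairs negative. The mean of -0.358 is therefore no separate result. Arrays of a number pair may share 1 sample, or another source of likeness that the other group lacks. In either of these cases, treating 12 arrays as independent overstates the certainty of the 788 calls. Part of the likeness may instead be shared by both groups. Same-numbered arrays correlated across groups at 0.297 to 0.545, and at 0.158 to 0.273 over probes above 0 on all arrays. How much is shared was not tested. With the replicate number as a block 809 probes passed, but that fit also takes arrays of a number pair as independent. The count of 9 does not rely on the independence of arrays within a number pair.

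**Figure D3:**
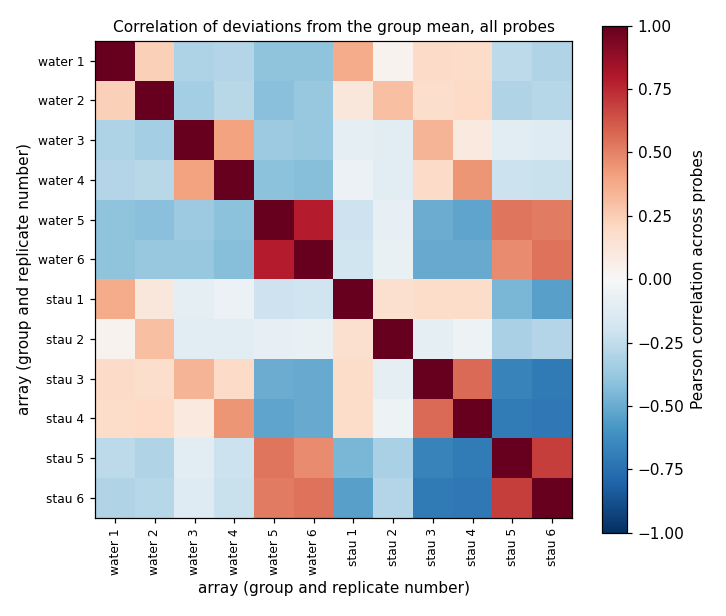
Pearson correlation across all probes of deviations from the group mean between each pair of the 12 arrays (both axes: group and replicate number; stau, staurosporine), with colour from -1 to 1. Blocks on the diagonal are number pairs, with a mean of 0.474, and the blocks joining water 5 and 6 with staurosporine 5 and 6 have a mean of 0.517.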

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

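The highest or lowest array of a group of 6 was checked against the other arrays for each named gene and for array medians and counts of probes at 0. In 3 of 96 groups 1 array lay far from the rest, where chance flags about 1 group in 20. For AT4G05030, water replicate 3 had a normalized intensity of 0.1, with the nearest water array at 0.0417. Both lie below the group mean of 0.333 after staurosporine. For AT3G52960, the chloroplast peroxiredoxin IIE, staurosporine replicate 3 had 0.165 and the nearest array 0.275. For FATB, staurosporine replicate 3 had 0.317 and the nearest array 0.112. No explanation was tested for these 3 values.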

How the results depend on the processing

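Settings fixed at the start kept the count of changed probes between 566 and 1115 (main 788), apart from averaging numbers 1 and 2, 3 and 4, 5 and 6 (9), an adjusted p of 0.01 (361) and a minimum log2 change of 1 (369), the last 2 by construction. With the replicate number as a block the count was 809, 681 of them shared, so the block ended 107 of the 788 calls, among them those of AT3G13120 (adjusted p 0.0767), GH9B16 (0.0844), LAS (0.0540) and DAL1 (0.0557). Of the 30 genes of largest change, 25 passed without further normalization, 24 with centring, 27 with cyclic loess, and 28 with array weights or the brightness block, where AT1G24040 (0.159 and 0.0733) and AT2G43180 (0.128 and 0.0722) lost the call. Leaving out 1 array gave 614 to 751. Of 8 alternatives chosen after the data were seen, averaged pairs gave 106 with an offset, 182 without the dimmest probes, 5 with array brightness as a block and 2 with the number pair as a block, the number pair as a random block gave 191, and dropping numbers 5 and 6 gave 377. A common floor gave 858 and the brightness block over 12 arrays 711. Averaging leaves fewer values and removes the likeness of mates; why the offset and filter raise its count was not tested. No setting turned the sign of any of the 30 genes of largest change, which had been picked on these same arrays. Of these genes, 7 passed with averaging and offset, 14 of 23 with averaging and the filter, 12 with the random block, 18 without numbers 5 and 6, and 0 with averaging alone or with averaging and either block. Of 1358 alternative values of all named genes, 1098 kept direction and side of the threshold, 224 lost the call, 24 gained it and 12 reversed.

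The cause of reversals was not tested; none concerned a called gene. Centring gave -0.27 for PSBW, -0.048 for AT1G74470 and -0.22 for AT5G65220. Deposited values gave 0.073 for NTRC, 0.12 for AT2G04700 and 0.19 for AT1G64510. AT2G04700 was 0.14 with array weights and 0.0069 with either brightness block. AT1G64510, nearly always at 0, was 0.00088 with an offset, averaged or not. AT5G65220 ran from -0.00772 (without water replicate 1) to 0.16 when 1 array was left out. The plastid ribosomal list, whose test is not read because 1 of its 5 genes was nearly always at 0, turned sign in limma's camera with centring (a p of 0.979), averaging (0.997), array weights (0.631), averaging with offset (0.954) and the brightness block (0.879, averaged 0.895). It also turned without numbers 5 and 6 (0.806), and leaving out 1 array gave 0.797 to 0.995. The list could not be tested without the dimmest probes, where under 5 of its genes remained. The mean correlation within number pairs stayed between 0.295 and 0.474.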

Other observations

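The tests on number pairs, on arrays 5 and 6, on array brightness and on the photosynthesis genes were chosen after the values they measure had been seen; the counts of random splits were planned.

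Among called genes with a symbol in the gene table, chosen here after their values were seen, 10 were higher and 16 lower after staurosporine. NdhS, a subunit of the chloroplast NADH dehydrogenase-like complex, rose from 6.74 ± 1.69 to 15.5 ± 2.37 (n = 3 number pairs), a log2 change of 1.22 ± 0.17 with a limma adjusted p of 0.000582 over 12 arrays and 0.118 after averaging. SIRB, the sirohydrochlorin ferrochelatase of siroheme synthesis, rose 2.30-fold, LpxA, an acyltransferase of the lipid A type pathway, 1.97-fold, and FZL, a dynamin-like protein of thylakoids, 1.96-fold. Transcripts of RAP74, a subunit of the general transcription factor TFIIF, and of LAS, a GRAS regulator of axillary meristems, rose 1.79-fold and 1.40-fold, but with the replicate number as a block the adjusted p of LAS went from 0.0211 to 0.0540. Besides the genes of the report, the falls took in pyruvate orthophosphate dikinase (PPDK, 1.70-fold), cyanase (CYN, 1.79-fold), the copper-binding chloroplast protein CUTA (1.80-fold), the calmodulin-like protein CML30 (1.88-fold) and tripeptidyl peptidase II (TPP2, 2.22-fold). Both measured PRA1 genes, which encode prenylated RAB acceptors, fell, PRA1.B3 by a log2 change of -0.73 and PRA1.B6 by -0.67. Of 4 measured endoglucanase genes of family GH9B, GH9B11 (-1.24) and GH9B16 (-0.55) passed, GH9B16 only without the replicate block (adjusted p 0.0401, with the block 0.0844), while GH9B12 (-0.54, adjusted p 0.295) and GH9B8 (-0.45, adjusted p 0.568) did not. None of the genes in this paragraph passed with the number pairs averaged, where the lowest adjusted p was 0.109, for GH9B11. These families were noticed in the values and were not tested as sets.

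With pairs averaged and an offset added, a setting chosen after the data were seen, 106 probes passed, 105 of them among the 788, and 18 carry a single gene. They include PSAN (adjusted p 0.0183), AT1G34270 (0.0198), AT3G57120 (0.0285), CML30 (0.0355) and GH9B11 (0.0360). CSLA01, a cellulose synthase-like gene, passed there (0.0216) without passing over 12 arrays (0.199).

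The drop from 788 calls to 9 on averaging number pairs is the pattern a reader would most want explained. Fewer values per group were not the whole cause, since averaging numbers 1 and 4, 2 and 5, 3 and 6 left as few values and gave 647 calls. Likeness of mates with no treatment effect is argued against for the 9 probes that passed with averaging alone. That was the only planned setting that counts each number pair once. Of the 788 probes, 277 passed in at least 1 of 6 settings that average number pairs or model the likeness of mates. These were averaging alone (9 of the 788), averaging with the offset (105), without the dimmest probes (180) with the brightness block (5) or with the number pair as a block (2), and the random block (191), and all but the first were chosen after the data were seen. For the called probes other than the 9 it stays open, and 511 of the 788 passed in none of these settings. Only 10 splits of the arrays keep mates together, too few for a share under 0.05. Of these, 1, the real one, gave as many as 788 calls, with 469 the highest of the others. Over probes above 0 on all arrays the real split gave 848 calls and the highest other 22, and with a common floor 858 and 50. Whether mates are repeats of 1 sample cannot be told apart from other causes of likeness: the lowest correlation within a number pair was 0.157 against 0.186 for the highest between pairs over all probes, and the 2 kinds separated (0.167 against -0.093) only over probes above 0 on all arrays, a set chosen after the first comparison had failed.

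The split with 469 calls set the 6 arrays with the higher medians (0.416 and above; 4 staurosporine, 2 water) against the 6 with the lower (0.383 and below). These calls follow the floor that each array was given, since the same split gave 11 calls with a common floor and 6 with an offset. Of those 469 probes, 389 were listed at 0 on at least 1 array and 12 were also called by treatment, and over probes above 0 on all arrays the split gave 0 calls in limma. With this class as a block the treatment gave 711 calls, within the lower class 179 and within the higher class 268. The lower class holds only numbers 3 and 4 of staurosporine, and the higher class only numbers 5 and 6 of water. Each count within a class thus rests on 1 number pair in 1 group, which may be 1 sample.

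Arrays 5 and 6 deviated together across the groups, with a mean correlation of 0.517 over all probes. Over probes above 0 on all arrays it was 0.129 with an SD of 0.053, so values at 0 carried much of it, and whether they carried all of it stays open. At 6 of 6 numbers the water array correlated more with the staurosporine array of its own number than with that array's mate, which is consistent with a technical round shared by both groups, although plants grown or treated together would give the same. No biological explanation was tested.

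Of the lists on light harvesting, both photosystems, electron transport and the Calvin cycle, pooled after their members had been seen, 6 probes had a signal, including 1 probe whose genes all lie on these lists. Their median log2 change was -0.45, with p = 0.0386 in camera, p = 0.0820 with an estimated correlation and p = 0.0492 with number pairs averaged. The rotation test fry in limma, which does not compare the pool with other probes, gave a p of 7.6e-06 for a common direction and 1.13e-05 for change in either direction, or 0.00378 and 4.95e-05 with number pairs averaged. Of 10000 random sets of probes matched on mean level, 6.69% had a median as low, so a fall of probes of like brightness could give the same. The pool as first formed had 7 members, with 1 listed at 0 on all 12 arrays, and gave 12.6%. A pool of 8 redox probes formed in the same way had a median of -0.12. Its p in limma's camera was 0.875. A coordinated fall of photosynthesis transcripts is therefore only a hypothesis here, resting mainly on PSAN and LHB1B2. Off these lists, NdhS of the chloroplast NADH dehydrogenase-like complex went the other way, with a log2 change of 1.22 (limma adjusted p 0.000582 over 12 arrays). PSB27, also off the lists, had -0.80 without passing (0.077).

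In 100 random splits of the 12 arrays into 6 and 6, 1 split, the real one, gave as many as 788 calls and the highest other gave 2. Only 3 of the 100, the real one included, keep all number pairs together, and a split that parts mates puts the difference between pairs inside the groups, so these splits do not exclude chance for the count over 12 arrays. The split by array brightness with its 469 calls was not among those drawn. Of the 32 splits that part every pair of same-numbered arrays only 4 keep mates together, the real one included, too few for a share under 0.05, and the highest other of these gave 0 calls. For the 6 averaged values there are 10 splits, too few for a share under 0.05, and the real one gave 9 calls against 0 for the highest other. Over all 3439 probes, 1535 (44.6%) had the same sign in the 3 number pairs, where 25% would by chance if probes and pairs were independent.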
